A study of Homo sapiens with 6 samples.

How the data were processed

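Total RNA from 2 isogenic A375 melanoma lines was profiled with the nCounter PanCancer Progression panel, with 3 samples of the NRAS wild-type line and 3 of the NRAS Q61K line, per the labels. Samples were assigned to groups and replicate numbers by their titles. No treatment was applied and the labels name no batch or date.

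The deposited values are a normalized signal on a linear scale, 1 value per gene and sample, and what the authors did to make them was read from the values, since software, background and normalization settings were not given in the sources used here. The table has 784 rows, of which 770 are genes, 8 negative control probes and 6 positive control probes. Per the deposited values, each gene value equals a whole count minus a background, multiplied by 1 factor per sample, and is held at a minimum of 1. With the factors found, 100% of the gene values between 1.5 and 400 were whole within 0.03. The factors were 0.898, 0.903 and 0.898 in wild-type samples and 1.16, 1.11 and 1.12 in mutant samples. The background's fractional part is what a mean over 6 control probes would give, but its whole part cannot be read, so the raw counts are known only up to 1 constant per sample. The factor brings the geometric mean of the 30 housekeeping genes to between 728 and 733 in every sample. Control rows were background-subtracted and not scaled. Before scaling, the housekeeping geometric mean was 808 to 814 in wild-type and 627 to 661 in mutant samples, while the positive controls averaged 1396 to 1490 and 1329 to 1516 (geometric mean). A scaling of this kind sets the housekeeping genes equal, so that any true difference in them moves every other gene the opposite way.

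Gene symbols were matched to the gene table of the human reference assembly GRCh38.p14. All 770 gene rows matched, 755 by their current symbol and 15 through an older one, and symbols are printed as the table gives them. No coordinates were used, since the table names no genome build.

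The detection floor was the mean of the 8 negative control probes over all samples, 31.7, plus 2 SD of 49.0, which gives 129.7. It was set on unscaled control values and applied to each gene's mean over the 6 samples. Endogenous genes above it were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend) on log2(value + 1), with a 2-sided moderated test of mutant minus wild type and Benjamini-Hochberg adjustment. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. Where 1 line's mean was at or below the floor, the fold is given as a bound, the brighter line's mean divided by the floor, and no fitted fold is printed. Gene lists with at least 3 tested members were compared with the other panel genes by camera with a preset correlation of 0.01, by camera with an estimated correlation, and by fry, with adjustment over the 21 lists tested. The panel is itself a selected set of genes, so these tests compare a list with other panel genes and not with the transcriptome.

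The design, the alternatives, 22 gene lists and the rule for naming genes were fixed before the data were examined. The lists were RAS and RAF, ERK targets, PI3K and AKT, melanocyte lineage, dedifferentiated melanoma, mesenchymal, epithelial, collagen, basement membrane and matrix glycoprotein, integrin, matrix protease and inhibitor, angiogenic factor, hypoxia response, TGF-beta, BMP and SMAD, cytokine and chemokine, receptor tyrosine kinase, Wnt and Notch, cell cycle, metastasis suppressor, and endothelial, leukocyte, and fibroblast and mural markers. Some genes stand in several lists. The rule named, among genes past the threshold whose samples did not overlap between lines, the 5 with the highest rise and the 5 with the deepest fall, then the 2 members of each tested list with the smallest adjusted p, and every measured RAS and RAF gene, 48 genes in all. Results for some of these and other genes are not reported here. Other genes in the text were chosen after their values were seen. They are members that make up a count of 5 or fewer in a list, the members of a list that did not pass, single members of the collagen, integrin, hypoxia and ERK target lists, the fibroblast collagens, other marker genes, and the genes of the closing observations. Members of the cytokine and epithelial lists below the floor were also named in this way.

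On data simulated from the mean of each of the 454 tested genes over all samples with a replicate CV of 0.04, the fit recovered 20% of genes changed by 1.1-fold, 54% of those changed by 1.15-fold and 100% of those changed by 1.5-fold or 2-fold, and called 4 of 254 unchanged genes. Camera was run on data simulated from the same gene means, in which only a list of 15 genes was shifted, by 1.5-fold. It called that list and did not call an unshifted one. Genes varied independently there and the rest did not change, unlike the real data. The check therefore does not measure camera's power or error here. Replicates were compared by a chi-square test of their unscaled counts. Every pair differed by more than counting noise, with a chi-square per gene of 1.16 to 3.04, so no pair was counted as 1 sample deposited again. This does not show that samples came from separate cultures. The number of samples limits the precision.

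Alternatives tried were other pseudocounts, other floors, 3 other scalings, other variance priors, stricter thresholds, the replicate number as a block, leaving out each sample in turn, and, chosen after seeing the data, a floor from negative control probes A to F and counts without the sample factors. A count model was not run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.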

Results

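Expression of a cancer progression panel was measured in untreated cells of the human melanoma line A375, which carries the BRAF V600E mutation, and in an isogenic derivative that also carries NRAS Q61K, an activating mutation of the small GTPase NRAS. Both lines carry a luciferase reporter, per the line's catalogue name, and were sampled within 5 population doublings of being thawed. The NanoString nCounter assay counts fluorescent barcodes hybridized to target RNA without amplification. Each line gave 3 samples of total RNA, and each sample was read for 770 transcripts. Total counts after background subtraction and before scaling between samples were 1264604, 1224108 and 1239839 in the NRAS wild-type samples and 1158530, 1189677 and 1170017 in the NRAS Q61K samples. The median coefficient of variation of a tested gene was 3.48% in the wild-type line and 3.64% in the mutant line (n = 3 each). Pearson's r across genes, on the log2 scale, was at least 0.9961 within a line and at most 0.8154 between lines. NRAS and BRAF themselves were not analysed here, so the genotype was not checked against its own transcript.

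The comparison asked which panel genes differed between BRAF-mutant melanoma cells with and without the NRAS mutation. Of 740 endogenous genes, 454 were above the detection floor of 129.7 normalized counts, and 377 of them differed at an adjusted p under 0.05 (limma). Of these, 282 were higher in the mutant line and 95 were lower. A change of at least 2-fold was fitted for 84 of the higher genes and 21 of the lower genes, and one of at least 4-fold for 36 and 9. The samples of the lines did not overlap for 382 genes, where chance gives 10% of genes. The excess of higher genes depended on the scaling between samples. As deposited, 74.8% of changed genes were higher and the median log2 difference of the tested genes was 0.32, or 1.25-fold. Without the scaling factor of each sample 175 genes were higher and 160 lower, with a median of -0.0079. After rescaling to equal medians 149 were higher and 206 lower, and after quantile normalization 153 and 205. Equalising the sample medians took 0.451 from every log2 difference, more than the median of 0.32, and left a median of -0.13. Quantile normalization left -0.12. Both thus overshoot the panel median, and a gene slightly above it, such as RB1 at 0.325 as deposited, was called lower after median rescaling. Across these 4 scalings, 144 of the 282 higher genes held their call. The other 3 lower the log2 difference of every gene or, for quantile normalization, of 450 of 454, so they test higher calls, and that all 95 lower calls held follows almost by construction. Log2 differences are given on the deposited scale, and values relative to the panel median have the shift of 0.32 subtracted.

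**Figure D1:**
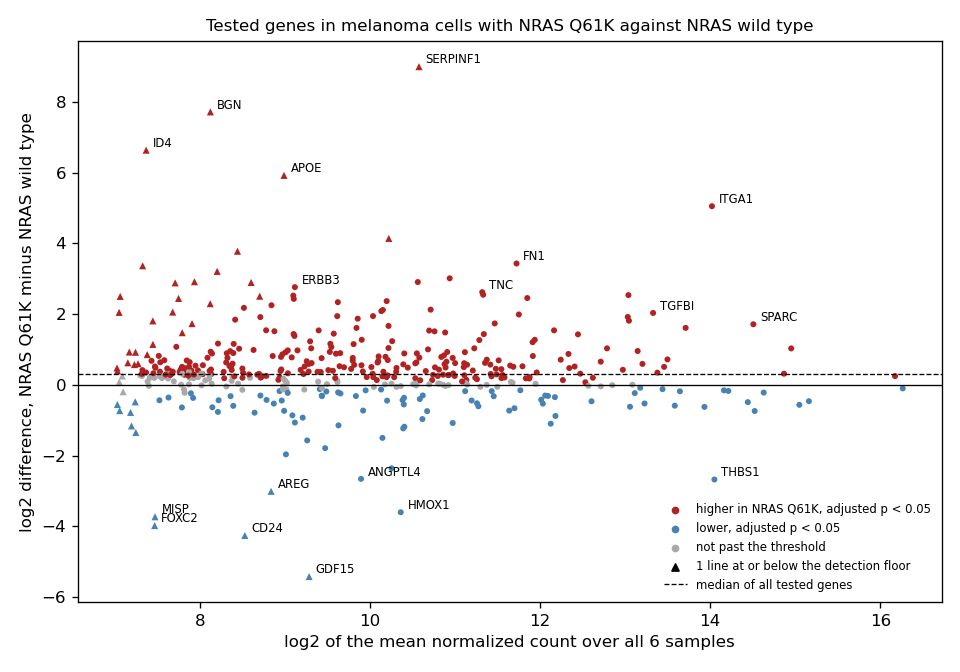
Log2 difference of each tested gene (NRAS Q61K minus NRAS wild type, n = 3 each) against log2 of its mean normalized count over the 6 samples, with colours for the 282 higher and 95 lower genes and a dashed line at the median of 0.32. Triangles mark genes with 1 line at or below the detection floor, whose plotted difference depends on the pseudocount, and ITGA1 and THBS1 stand out among bright genes.

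Among the largest rises were secreted and matrix-associated products that were below the floor in the wild-type line. SERPINF1, which encodes the anti-angiogenic pigment epithelium-derived factor, went from 6.58 ± 5.03 to 3045 ± 38.9 normalized counts (SD, n = 3), at least 23.5-fold higher (adjusted p = 2.33e-05). The apolipoprotein gene APOE was at least 7.72-fold higher, at 1000.3 ± 35.5 against 15.5 ± 1.92. BGN, encoding the proteoglycan biglycan, was at least 4.29-fold higher, and ID4, an inhibitor of basic helix-loop-helix transcription factors, at least 2.53-fold. ITGA1, the collagen-binding integrin alpha-1 subunit, was measured in both lines and was 33.2-fold higher, at 32266 ± 258 against 971 ± 41.9 (adjusted p = 6.90e-09). The largest falls included GDF15, a stress-induced cytokine of the TGF-beta superfamily, with 1218 ± 30.7 in wild-type cells and 28.9 ± 11.3 in mutant cells, at least 9.39-fold lower. CD24, a cell-surface glycoprotein, was at least 5.41-fold lower, the forkhead factor FOXC2 at least 2.57-fold and the actin-bundling protein gene MISP at least 2.55-fold. HMOX1, encoding the haem-degrading enzyme haem oxygenase 1, was 12.1-fold lower, at 199.9 ± 10.2 against 2430.4 ± 55.4 (adjusted p = 3.36e-08). Every one of these genes kept its direction and its call under all 4 scalings.

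Genes of the extracellular matrix and its receptors were mostly higher in NRAS Q61K cells. Of 8 tested collagen genes 7 were higher and COL5A1 did not pass, at 345 ± 11.4 and 354 ± 7.26, and was lower under the other 3 scalings. COL4A1, a basement membrane collagen, was 3.98-fold higher (5505 ± 115 against 1382.5 ± 50.2) and COL5A2, a fibrillar collagen, 2.42-fold. COL6A1, a beaded-filament collagen named after its values were seen, was 5.86-fold higher. Of 21 basement membrane and matrix glycoprotein genes, 17 were higher and 3 were lower, or 13 and 4 after median rescaling. FN1, encoding the adhesive glycoprotein fibronectin, was 10.8-fold higher at 6186 ± 168 against 572 ± 38.3, and SPARC, a collagen-binding matricellular protein, 3.29-fold higher. The lower members were THBS1, LAMA1 and SPP1, the last of which encodes osteopontin and was 2.34-fold lower. THBS1, encoding the matricellular glycoprotein thrombospondin 1, was 6.38-fold lower at 4596 ± 43.6 against 29313 ± 465 (adjusted p = 2.21e-08). Of 13 tested members of the integrin list 11 were higher and 1 lower, or 7 and 3 after median rescaling. The list also holds ILK and PTK2, which encode signalling partners of integrins and not integrin subunits. Both were among the higher members on the deposited scale. ITGA6, a laminin receptor subunit, was 3.52-fold higher at 13161 ± 186 against 3736 ± 47.1. ITGA2, a collagen receptor subunit, was the member that was lower, by 1.29-fold. Relative to the panel median, the list medians were 1.30 for collagen, 0.58 for matrix glycoproteins and 0.28 for the integrin list (log2). With camera at its preset correlation, none of these lists stood above the other panel genes on the deposited scale (adjusted p = 0.121, 0.296 and 0.121). The collagen list passed after median rescaling (adjusted p = 0.0207), quantile normalization (0.0217) and without the sample factors (0.0476), and the glycoprotein list after median rescaling (0.0496), within ranges over the alternatives of 0.0207 to 0.187 and 0.0496 to 0.596. Neither passed with an estimated correlation on the deposited scale (adjusted p = 0.766 for each).

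**Figure D2:**
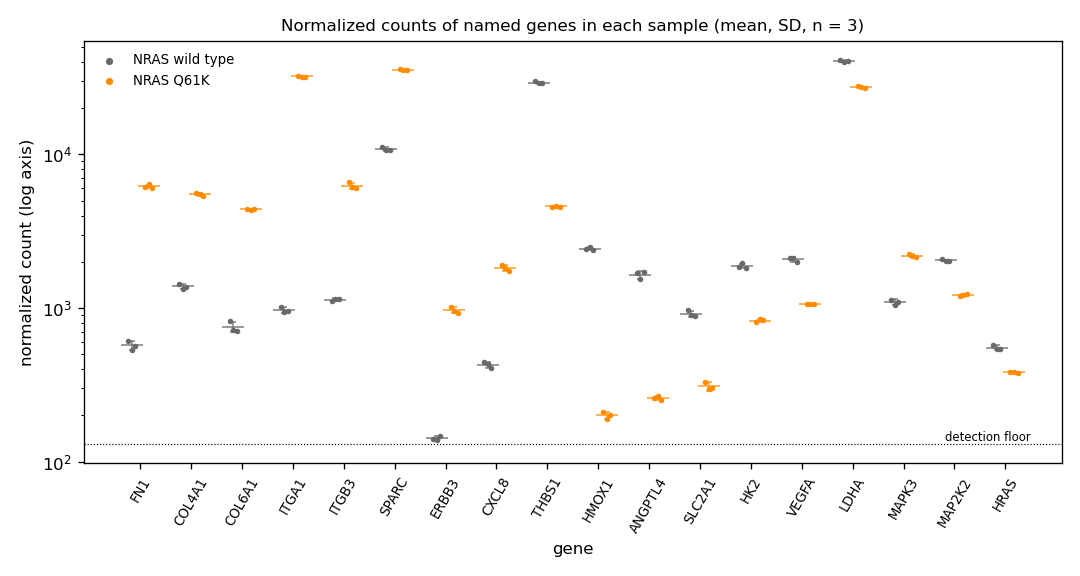
Normalized counts (log axis) of 18 genes in each of the 3 NRAS wild-type samples (grey) and 3 NRAS Q61K samples (orange), with bars for the mean and SD and a dotted line at the detection floor of 129.7. For each gene the 3 samples of a line lie close together and apart from the other line, as for FN1, with means of 572 and 6186, and HMOX1, with means of 2430.4 and 199.9.

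Hypoxia-response genes were lower in the mutant line. Of 15 tested, 11 were lower and 3 were higher, and PDK1 did not pass, at 649 ± 8.84 and 693 ± 33.5, and was lower under the other 3 scalings. HMOX1, a gene better known for its response to oxidative stress, and ANGPTL4, an inhibitor of lipoprotein lipase, fell most, with ANGPTL4 6.30-fold lower at 259.97 ± 8.06 against 1643 ± 86.8 (adjusted p = 7.06e-08). Of members named after their values were seen, the glucose transporter gene SLC2A1 was 2.96-fold lower, and the glycolytic enzyme genes HK2 2.27-fold, PGK1 1.54-fold and LDHA 1.48-fold lower. VEGFA, encoding a vascular growth factor, was 1.95-fold lower, and HIF1A, encoding the oxygen-regulated transcription factor subunit, was 1.09-fold lower. Among the higher members were NDRG1 (1.58-fold) and VHL (1.41-fold), of which VHL did not pass after median rescaling or quantile normalization. The list's median was -0.46 and lay -0.78 from the panel median (log2). This was the only list that camera placed apart from the other panel genes on the deposited scale (adjusted p = 0.000146), and it did not pass with an estimated correlation (adjusted p = 0.637). With the preset correlation the adjusted p rose to 0.0207 after median rescaling, 0.0217 after quantile normalization and 0.0115 without the sample factors, within a range of 0.00011 to 0.0217 over the alternatives.

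Of 17 angiogenic factor genes 9 were higher and 7 were lower, including THBS1 and ANGPTL4. The list pools ligands, receptors and THBS1, which encodes an inhibitor of angiogenesis, so its split gives no direction of angiogenic activity. CXCL8, encoding the neutrophil-attracting and angiogenic chemokine interleukin 8, was 4.25-fold higher at 1818 ± 74.0 against 427 ± 19.4. The split of this list became 4 and 9 without the sample factors and 3 and 10 after median rescaling (camera adjusted p = 0.237).

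Members of the RAS, MEK and ERK cascade moved in different directions. MAPK3, encoding ERK1, was 2.01-fold higher (2193 ± 41.4 against 1092 ± 47.7). HRAS was 1.44-fold lower, MAP2K2, encoding MEK2, 1.67-fold lower and MAP2K1, encoding MEK1, 1.13-fold lower. Of 10 tested genes known to respond to ERK signalling, 4 were higher and 6 were lower (camera adjusted p = 0.121), or 3 and 6 after median rescaling. AREG, encoding the epidermal growth factor receptor ligand amphiregulin, was at least 6.28-fold lower, at 101 ± 8.71 against 814 ± 15.1. IL11, encoding interleukin 11, was 3.60-fold higher at 534 ± 12.1 against 148 ± 11.7. Named after their values were seen, the transcription factor genes JUN and MYC were 3.45-fold and 1.90-fold lower and ETV4 was 1.91-fold higher, and PLAU was higher on the deposited scale alone. Of 10 PI3K and AKT genes 6 were higher and PIK3R2 was lower by 1.08-fold (camera adjusted p = 0.840). PIK3CA, the catalytic subunit of PI3-kinase alpha, was 1.54-fold higher (770.4 ± 4.36 against 501 ± 16.2), but the list split 5 and 4 without the sample factors and 4 and 5 after median rescaling.

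Of 19 melanocyte-lineage genes listed only 3 were on the panel, and all 3 were tested and higher (camera adjusted p = 0.296). The other listed genes were not measured, so these 3 do not show how the lineage as a whole differed. ERBB3, a receptor of the neuregulin ligands, was 6.80-fold higher at 968 ± 39.6 against 141 ± 4.42. MCAM, an adhesion molecule of melanoma cells, was 1.70-fold higher, and SOX9, a neural crest transcription factor, 1.69-fold higher. Of 11 genes of dedifferentiated melanoma 7 were higher, and EGFR, JUN and THBS1 were lower (camera adjusted p = 0.993), a split of 7 and 4 after median rescaling. TNC, encoding the matrix glycoprotein tenascin C, was 6.16-fold higher at 4398 ± 139 against 713 ± 27.1. Of 15 mesenchymal genes 11 were higher, FN1 and SPARC among them, and FOXC2, SNAI2 and MMP3 were lower (camera adjusted p = 0.694), against 9 and 5 after median rescaling. SNAI2, which encodes the transcription factor Slug, was at least 1.20-fold lower. Of 24 epithelial genes on the panel 6 were tested, and CLDN4, CLDN7 and DSC2 were higher (camera adjusted p = 0.840), but 1 was higher and 1 lower after median rescaling. The other members were below the floor. With no floor KRT7 (122 and 42.6 counts in wild-type and mutant cells), OVOL2 (91.4 and 30.7) and CGN (57.5 and 2.44) were called lower (limma). MUC1 (74.9 and 103.7) and SPINT1 (16.4 and 29.8) were called higher, apart from members at the minimum in every sample. CLDN4, a tight junction claudin, was 4.35-fold higher at 1848 ± 39.3 against 426 ± 45.7 and held its call under every scaling. CLDN7, another claudin, was 1.25-fold higher as deposited, and its direction turned under the other 3 scalings, where it did not pass.

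Of 13 receptor tyrosine kinase genes 10 were higher, while EGFR, EPHA2 and MET were lower (camera adjusted p = 0.773), against 8 and 3 after median rescaling. The fibroblast growth factor receptor gene FGFR1 was 3.67-fold higher at 1456 ± 49.4 against 396 ± 16.2, and MET, encoding the hepatocyte growth factor receptor, was 1.65-fold lower. Of 11 cytokine and chemokine genes 9 were higher, CXCL8 and IL11 among them, and CXCR4 and IL1B did not pass, at 128 ± 9.99 and 138 ± 30.8 counts for CXCR4 and 255 ± 5.78 and 279.9 ± 28.7 for IL1B (camera adjusted p = 0.296). After median rescaling 7 were higher and 2 lower. IL1B was lower under all 3 other scalings and CXCR4 after quantile normalization. Members below the floor were not tested. Among them IL18 had 139 counts in wild-type and 12.1 in mutant cells, at least 1.07-fold lower. With no floor IL18, PTGS2 and IL6 were called lower (limma). TNFSF12 and IFNG were called higher there, apart from members at the minimum in every sample. Of 25 TGF-beta, BMP and SMAD genes 17 were higher and 5 were lower (camera adjusted p = 0.823), a split of 10 and 10 after median rescaling. TGFBI, an adhesive matrix protein gene induced by TGF-beta, was 4.10-fold higher at 16541 ± 52.8 against 4032 ± 93.0. The lower members were GDF15, THBS1, FST, ID1 and TGFB2. Of 7 Wnt and Notch genes 6 were higher (camera adjusted p = 0.495), and after median rescaling 3 were higher and 4 lower. SFRP1, encoding a secreted Wnt antagonist, was 2.92-fold higher and CTNNB1, encoding beta-catenin, 1.65-fold higher.

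Of 20 matrix protease and inhibitor genes 12 were higher and ADAMTS1, CTSK, CTSL, MMP3 and PLAUR were lower (camera adjusted p = 0.815). After median rescaling 5 were higher and 11 lower, and without the sample factors 6 and 8. ADAMTS1, a secreted metalloprotease, was 3.90-fold lower at 210.2 ± 8.80 against 822 ± 12.2, and the metalloprotease inhibitor gene TIMP2 was 1.86-fold higher. Of 15 metastasis suppressor genes 9 were higher and BRMS1, CADM1, DLC1 and NME1 were lower (camera adjusted p = 0.840), a split of 6 and 6 after median rescaling. The scaffold protein gene AKAP12 was 2.70-fold higher and NME4, a mitochondrial nucleoside diphosphate kinase, 3.18-fold higher, while its relative NME1 was 1.44-fold lower. Of 4 cell cycle and growth arrest genes 2 were higher, RB1 among them, while MYC and the cyclin-dependent kinase inhibitor gene CDKN1A were lower, CDKN1A by 1.53-fold at 6729.8 ± 54.2 against 10314 ± 229 (camera adjusted p = 0.544). RB1 was lower after median rescaling and quantile normalization.

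**Figure D3:**
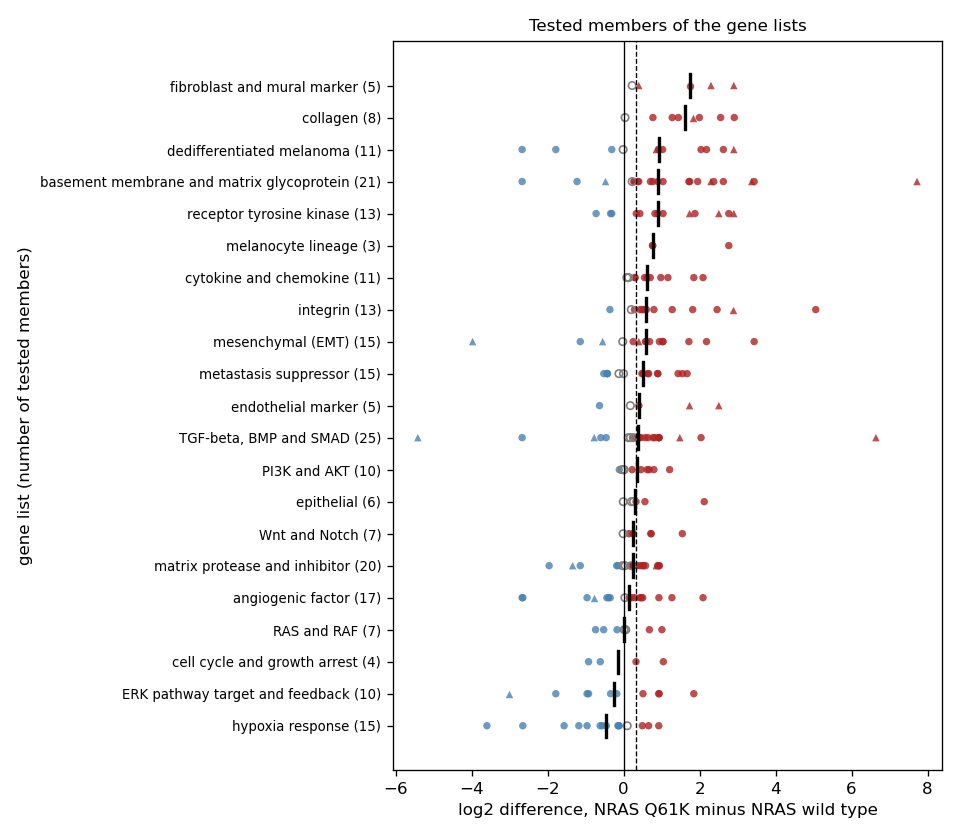
Log2 difference (NRAS Q61K minus NRAS wild type) of the tested members of 21 gene lists, filled when the adjusted p was under 0.05 (red higher, blue lower) and open otherwise, with a black bar at each list's median and a dashed line at the panel median of 0.32. Triangles mark members with 1 line at or below the detection floor, and the hypoxia-response list has the lowest median, -0.46.

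Markers of other cell types were mostly near or below the floor. Of 12 fibroblast and mural markers on the panel 5 were tested and 4 were higher, among them CSPG4, a proteoglycan that melanoma cells also express, 3.34-fold higher at 4355 ± 102 against 1303 ± 24.2, and PDGFRB, at least 5.29-fold higher (camera adjusted p = 0.326). LUM and FAP were the other higher members, and FAP turned lower after quantile normalization, while DCN did not pass, at 216 ± 6.68 and 255 ± 46.5. Beside the rise of collagen genes above, the fibrillar collagens most abundant in fibroblasts stayed below the floor in mutant cells, with 19.0 ± 5.56 counts for COL1A1 and 21.9 ± 5.91 for COL3A1, and COL1A2 at the table's minimum in both lines. Of 16 endothelial markers 5 were tested (camera adjusted p = 0.993). FLT1 and KDR, receptors of vascular endothelial growth factors, were at least 2.85-fold and 1.76-fold higher, PECAM1 was 1.32-fold higher on the deposited scale alone, ROBO4 was 1.55-fold lower, and CD34 did not pass, at 258 ± 21.1 and 294 ± 44.7, and was lower after quantile normalization. Of 7 leukocyte markers ITGB2 alone was tested and did not pass, at 219 ± 28.0 and 251 ± 21.7, though it was lower after median rescaling, and the pan-leukocyte gene PTPRC stood at the minimum in both lines (1, or 1 times the sample's factor, in each sample).

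Counts of changed members adjusted over the list alone were equal to those over all tested genes for each of the 22 lists. With an estimated correlation camera placed 0 lists past the threshold, and 0 at an unadjusted p under 0.05, against 1 past the threshold with the preset correlation. Fry called 20 of 21 lists directional and 21 mixed, but fry does not compare a list with the other panel genes, so the shift of the whole panel enters it. Camera's direction was down while the list's median was above 0 for the dedifferentiated melanoma, metastasis suppressor, matrix protease, angiogenic and RAS lists. Fry's direction was down while the median was above 0 for the angiogenic and RAS lists (fry adjusted p = 0.00129 and 0.0422). It was up while the median was below 0 for the cell cycle list, which did not pass (fry adjusted p = 0.271). Relative to the panel, median and mean also differed in sign for the PI3K, TGF-beta, epithelial, Wnt and metastasis suppressor lists. With members below the floor in 1 line set at their bound, the collagen median was 1.36 in place of 1.62 and the receptor tyrosine kinase median 0.82 in place of 0.90, and the other list medians did not move. Each genotype was represented by 1 line, and no label says that its 3 samples came from separate cultures, so the p-values measure the spread between these samples, which may be technical.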

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

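The tests of the housekeeping scaling, of the choice among housekeeping genes, of mural cells and of hypoxia-inducible factor activity were chosen only after the results were seen, and the fibroblast test, planned for fibroblasts or mural cells, was then narrowed to fibroblasts.

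Negative control probes G and H, which match no human transcript by design of such panels, averaged 97.3 and 128.2 counts over the 6 samples, where the other 6 negative probes averaged at most 20.7. They set most of the detection floor of 129.7, which would be 20 from probes A to F. The housekeeping genes, which served as the scaling reference and entered no comparison, were not uniform: 21 of 30 differed between the lines, 12 higher and 9 lower, with log2 differences from -0.46 to 0.62 (SD 0.26). The 0.62 belongs to CC2D1B, below the floor at 17.3 and 27.2 counts, and of the 28 above the floor 20 differed, 11 higher and 9 lower, from -0.46 to 0.31 (SD 0.24).

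More genes were higher than lower in NRAS Q61K cells, with a median log2 difference of 0.32. Without the factor of each sample the median was -0.0079, so the excess comes with the housekeeping scaling. The excess did not hang on which of the 30 housekeeping genes were used. Of 10000 random sets of 15 of them, 0% brought the median to 0 or below (range 0.14 to 0.51). All these sets come from the same 30 genes, so they cannot tell whether the 30 as a set differ between the lines. Whether housekeeping transcripts truly fell per cell in the mutant line or the panel's genes rose stays open, and a biological difference between the lines remains untested, since these values hold no measure of RNA per cell. They hold no measure of the RNA loaded per sample either, so the unscaled counts are not a neutral reference.

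Matrix genes were higher in NRAS Q61K cells, with 7 of 8 collagen genes higher on the deposited scale. For the collagens the housekeeping scaling alone is argued against, as 7 were still higher after median rescaling and 1 was lower, from 0. By contrast, the higher and lower members went from 17 and 3 to 13 and 4 among matrix glycoproteins. In the integrin list, ILK and PTK2 included, they went from 11 and 1 to 7 and 3. Fibroblasts mixed into the mutant cultures are argued against, since the median of COL1A1, COL1A2, COL3A1 and DCN, transcripts abundant in such cells, was 20.5 counts, or 0.465% of the COL6A1 level of 4399, with DCN the highest at 255. Of 5 tested fibroblast and mural markers PDGFRB, CSPG4, LUM and FAP were higher, and mural cells stay open, since of PDGFRB, CSPG4, CNN1 and MYH11 50% were higher, while CNN1 lay at the minimum and MYH11 at 1.69 counts. A difference of the mutant cells themselves stays open too, and with 1 line per genotype the NRAS mutation may not be its source, as clonal differences between the lines would look alike.

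Hypoxia-response genes were lower in NRAS Q61K cells, 11 of 15 as deposited and 12 without the sample factors, which raise mutant values and so make no lower calls. Lower activity of the hypoxia-inducible factor is a candidate explanation. The test gave a median of -0.24 (log2, SE 0.44) for 7 further targets relative to the panel median, which leaves it open. PFKFB4 and FLT1 lay above the panel median, and MET, GPI, PKM, CXCR4 and PFKFB1 lay below it. Oxygen, cell density and medium at harvest are not given in the sources used here and were not tested.

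Splits of the 6 samples, 3 against 3, number 10, too few for a share under 0.05. The real split gave 377 changed genes, 282 higher, 95 lower and 172 changed list members, and it was the 1 split of 10 to give as many in each case, with 0 as the highest of the other splits (limma). At an unadjusted p under 0.05 the real split gave 379 genes and the other splits 0 to 3 (limma). Each other split mixes samples of both lines, so the line difference enters its residual spread and holds its counts down. The gap between the real and the other splits was therefore built in and does not measure chance. For lists past camera's threshold the real split gave 1 and the highest other split also gave 1, and 8 of the 10 splits gave as many, so the number of lists called does not set the real split apart.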

How the results depend on the processing

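The unscaled counts and the floor from negative control probes A to F were chosen after seeing the data. The count of changed genes stayed within 1.5 times of 377 under every alternative except the log2 threshold, from 334 at an adjusted p under 0.01 to 518 with no floor (740 genes tested). Higher and lower genes numbered 149 and 206 after median rescaling, 153 and 205 after quantile normalization, and 175 and 160 for unscaled counts, with 3, 2 and 2 lists past camera's threshold. The median log2 difference was then -0.13, -0.12 and -0.0079, and 53, 51 and 16 genes that were higher on the deposited scale became lower. These 3 scalings lower nearly every log2 difference, so they put higher calls to the test and hardly the lower ones. An absolute log2 difference of at least 1 left 105 genes, 84 higher and 21 lower, and 58 list members, fewer by construction. With an estimated correlation camera called 0 lists, fry 20 directional and 21 mixed, each a different question. Log2 differences turned below 0 under median rescaling, quantile normalization and unscaled counts for CLDN7 (-0.13, -0.13 and -0.0043) from 0.32 as deposited. The other 42 of 43 named genes reported kept their sign under every alternative. Leaving out 1 sample at a time gave at least 352 changed genes, 258 to 284 higher and 91 to 97 lower, 163 to 173 list members, and the hypoxia list each time. With the replicate block 392 genes changed, 299 higher and 93 lower. Deviations of same-numbered samples correlated at 0.22, 0.053 and 0.066, and 4 of 6 samples correlated best with their own number, so the numbers were not taken to pair the samples. With probes A to F the floor was 20 and 435 genes changed. The planned count tests (edgeR and DESeq2) were not run, because raw counts are known only up to 1 constant per sample. Genes below the floor are limited by background: 286 were not tested, of which 119 were called higher and 34 lower with no floor. Of the 119, 75 were at the minimum in every sample, and the scaling alone made that call, since the factor lifts a minimum of 1 in mutant samples. The 518 includes these 75.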

Other observations

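Of 257 tested genes in no list, 155 were higher in NRAS Q61K cells, 50 lower and 52 did not pass. Those named here were chosen after their values were seen, and each held its call under all 4 scalings. They follow no fixed list, so no theme was tested. PCOLCE, an enhancer of procollagen C-proteinase, was at least 17.4-fold higher (2259 ± 118 against 127 ± 10.9 counts, SD, n = 3), and EMILIN1, an elastic fibre glycoprotein, at least 5.00-fold. FREM2, a basement membrane protein, was at least 4.11-fold higher and MGP, matrix Gla protein, at least 3.34-fold. Also higher were the actin-severing protein gene GSN, 5.82-fold (14359 ± 57.9 against 2466 ± 62.4), FHL1 5.76-fold, the homeobox gene MEOX2 8.09-fold and WWTR1, which encodes the Hippo pathway coactivator TAZ, 3.06-fold. Lower genes were PTX3, the long pentraxin, 5.12-fold lower (399 ± 34.2 against 2042 ± 18.3), the myosin kinase gene MYLK 2.82-fold, the tumour suppressor gene NF2 2.11-fold and RUNX1 2.09-fold lower.

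Several genes under the floor on average were above it in 1 line. The integrin genes ITGA9 and ITGA11 stood at the minimum of 1 in wild-type cells and at 174 and 134 counts in mutant cells, at least 1.34-fold and 1.03-fold higher, whereas ITGB7 had 253 and 4.94 counts, at least 1.95-fold lower in mutant cells. The receptor gene IL1RL1 had 163 counts in wild-type cells and was at the minimum in mutant cells, at least 1.26-fold lower. These genes were not in the main test, and the fit with no floor gave them adjusted p-values of 5.99e-07, 1.17e-06, 0.002 and 1.15e-07 (limma). No explanation was tested for these values.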
